A study of Oncorhynchus mykiss with 20 samples.

How the data were processed

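Liver RNA of 20 rainbow trout was profiled, 10 fish of the ARS-KO strain and 10 of the House Creek strain, and strain and replicate number were taken from the submitters' labels. Per the labels' protocols, total RNA was extracted with TRIzol, standardized to 1 µg, treated with DNase I, depleted of ribosomal RNA with the Ribo-Zero Gold kit and made into libraries with the ScriptSeq v2 kit. The labels list a range of TruSeq indexes but do not say which fish had which, or which fish were processed together. Per the submitters' processing notes, CASAVA 1.8.2, Trim Galore 0.4.0, Bowtie2 2.2.5, eXpress 1.5.1 and DESeq2 were used, and the genome build and the parameters are not given in the sources used here.

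The deposited values are effective counts, that is, estimated counts of reads per lncRNA transcript, which the authors rounded to whole numbers, per the file headers and names. Among the tools in the processing notes, eXpress is the one that gives such values. It divides reads that fit several transcripts among them, so near-identical transcripts share reads and their individual counts are uncertain. Among the 193220 transcripts with counts, 92366 had exactly the same counts in all fish as at least 1 other transcript. This number has no minimum count and includes transcripts with very few counts, since only 15878 had a mean above 10. It therefore does not measure how many transcripts share sequence. The transcript identifiers hold 20 tags that match the 20 sample codes, which reads as if the set had been assembled fish by fish, and 61.1% of the transcripts carry a House Creek tag. Of the identifiers 0 matched the gene table at hand, so names, positions and strand of the transcripts are not used here, and the 22 gene lists fixed beforehand were not run. Transcripts are reported by the last 2 parts of their identifiers.

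Analyses used R 4.3.3. Strains were compared with edgeR 4.0.16 (quasi-likelihood F test, TMM normalization, filterByExpr with a minimum count of 10 and a minimum total of 15), with Benjamini-Hochberg adjusted p under 0.05 as the threshold, two-sided, and the log2 fold change as ARS-KO minus House Creek. Standard errors are the fold change divided by the square root of F. The filter kept 10513 transcripts, which hold 95.1% of the counts, and the biological coefficient of variation was 1.09. The same test compared code prefixes within each strain (T11 minus T9, T23 minus T17). CPM values are TMM-scaled. Distances and principal components used log2 CPM with a prior count of 2. Differences of means were tested with 100000 random permutations. Intervals were not computed for single counts. The floor of 3 is in effective counts, not reads, and covers counting error only. No 2 libraries were duplicates, since Spearman correlations between fish ran from 0.438 to 0.756 over transcripts with a mean of at least 10 counts.

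Totals ranged from 5110000 to 18930000 counts per fish. On simulated counts for the strain comparison, with 200 of 10513 transcripts changed, the test recovered 4% of those changed by a log2 fold of 1, 24% at 2, 62% at 3 and 82% at 4, with 5 false among 91 calls and 0 calls when nothing was changed. For the ARS-KO prefixes it recovered 0%, 0%, 4% and 24% at the same sizes among 9991 transcripts, and for the House Creek prefixes 0%, 2%, 8% and 30% among 13850. Small changes were thus mostly out of reach at this depth and spread. The simulated fish were drawn independently, without correlation within prefixes, so the simulated false calls do not give the error rate for these fish. Spread was estimated without groups, so differences between prefixes counted as noise. Only transcripts above a minimum mean count were changed.

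The rule for naming transcripts without gene names was set before the data were examined, as were the main tests and most alternatives: the called transcript of largest fold change and that of lowest p in each direction, the former with a mean of at least 1 CPM in a strain and 9 of 10 fish beyond the median of the other strain, and the 2 of lowest p for each prefix comparison. In the strain comparison t114l|3755 met both parts of the rule. Alternatives were other normalizations, filters, tools (DESeq2 1.42.0, limma 3.58.1), handling of code prefixes, thresholds and fish left out. DESeq2 was run on all transcripts with a count and used its own filter in place of filterByExpr, so tool and filter changed together. Added after the data were seen were fits without 7 or 4 fish, surrogate variables (sva 3.50.0), libraries thinned to one total, the naming of t174l|2056 and the rule for transcripts high in the same 4 fish. On/off transcripts were defined in 2 ways, and both are reported. Figures were drawn with matplotlib 3.10.9.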

Results

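Long non-coding RNA (lncRNA) transcripts were counted in the livers of 20 rainbow trout (Oncorhynchus mykiss). ARS-KO fish come from a line bred to tolerate feed made from plants, and House Creek served as the control strain. From each strain 10 fish were fed a plant-meal diet in replicate tanks for 12 weeks before the liver was sampled. Each fish carries a sample code that begins with T9 or T11 in ARS-KO and with T17 or T23 in House Creek, with 5 fish per code prefix. The meaning of the prefix is not given in the sources used here. If it marks the tank, each strain had 2 tanks, fish of a prefix are not independent, and the p-values over 10 fish per strain are too small. The same 289289 lncRNA transcripts were listed for every fish, and 193220 of them had a count in at least 1 fish. They carry assembly-style identifiers that are not paired with gene names or genome positions, so few are named individually here.

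Counts assigned to these transcripts came to 5885000 ± 560400 per ARS-KO fish (SD, n = 10; range 5110000 to 6547000) and 9185000 ± 3756000 per House Creek fish (SD, n = 10; range 5391000 to 18930000). The difference of -3300000 counts, ARS-KO minus House Creek, passed a permutation test although the ranges overlapped and the House Creek SD was larger than the difference (two-sided, p = 0.00043, adjusted p = 0.00215 over 5 depth measures). Transcripts with at least 1 count numbered 34495 ± 8907 in ARS-KO and 45042 ± 10603 in House Creek (SD, n = 10; permutation p = 0.0241, adjusted p = 0.0402). After every library was thinned to 5110340 counts, the numbers were 33829 ± 8686 and 41742 ± 8405 (permutation p = 0.053, adjusted p = 0.0662), which did not pass the threshold. The 100 most abundant transcripts of each fish took 43.7% ± 3.64 of its counts in ARS-KO and 38.4% ± 4.38 in House Creek (SD, n = 10; permutation p = 0.0111, adjusted p = 0.0278). One transcript alone took 4.59% ± 3.17 of the counts on average over the 20 fish, ranging from 0.153% to 12.4%.

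**Figure D1:**
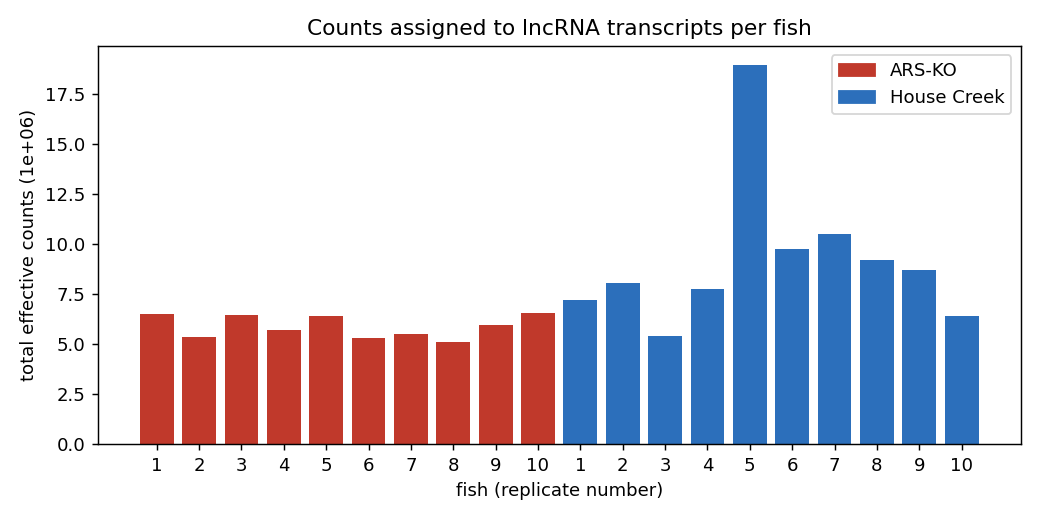
Total effective counts assigned to lncRNA transcripts in each fish, in units of 1e+06 counts, with 1 bar per fish and colour by strain. ARS-KO fish lie between 5110000 and 6547000, and House Creek replicate 5 is the deepest at 18930000.

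The largest axis of variation among the livers did not follow strain. A principal component analysis of the 10513 transcripts that passed the count filter put 26.3% of the variance on component 1, on which ARS-KO averaged -9.13 ± 111 and House Creek 9.13 ± 82.7 (SD, n = 10; permutation p = 0.686, adjusted p = 0.686 over 3 components). Scores on this axis left a gap between -73.9 and 14.2. Below it lay 7 fish, ARS-KO replicates 1, 2, 3 and 5 and House Creek replicates 1, 6 and 9. Of the 5 T9 fish 4 lay below the gap, against 0 of 5 for T11, 1 of 5 for T17 and 2 of 5 for T23. Component 2, with 12.8% of the variance, averaged 46.8 ± 59.8 in ARS-KO and -46.8 ± 31.3 in House Creek (permutation p = 0.00041, adjusted p = 0.00123). Both prefixes of a strain lay on its side of component 2, at 58.7 ± 80.9 for T9, 35.0 ± 34.0 for T11, -60.4 ± 13.0 for T17 and -33.3 ± 39.7 for T23 (SD, n = 5). On the third axis (7.76% of the variance; permutation p = 0.0109, adjusted p = 0.0164) T9 (-6.30 ± 48.4) and T17 (-5.44 ± 26.0) were close, and the strain difference came from T11 (-50.8 ± 26.1) and T23 (62.5 ± 31.2). These permutations exchanged fish freely and ignored code prefixes. Fish of the same strain and code prefix had a mean Spearman correlation of 0.712, fish of the same strain with the other prefix 0.620, and fish of different strains 0.628. These correlations are across transcripts, which are not independent replicates.

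**Figure D2:**
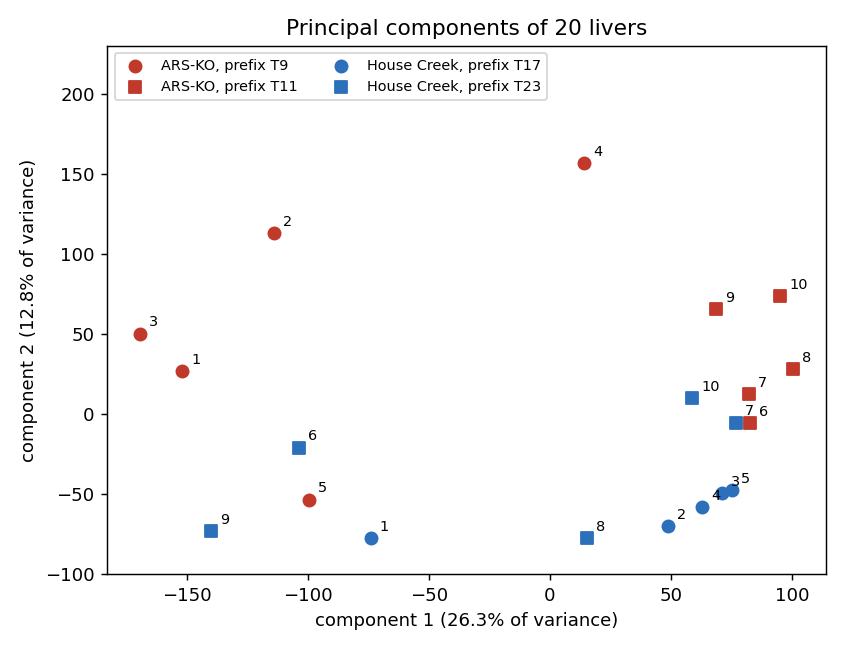
Scores of the 20 livers on the first 2 principal components of log2 CPM, with colour for strain, marker for code prefix and the replicate number beside each point. Component 1 (26.3% of variance) leaves 7 fish of both strains below -73.9, while component 2 (12.8%) averages 46.8 in ARS-KO and -46.8 in House Creek.

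The comparison of strains asks which liver lncRNAs differ between fish selected for growth on plant-based feed and control fish when both eat that feed. A small set of transcripts differed: 13 were higher and 7 were lower in ARS-KO among 10513 tested. Transcript t114l|3755 was assigned almost no counts in House Creek livers, at 0.327 ± 0.547 CPM, and stood at 58.5 ± 48.8 CPM in ARS-KO (SD, n = 10 each). In the opposite direction, t235l|18680 fell from 192 ± 66.1 CPM in House Creek to 12.7 ± 9.19 CPM in ARS-KO, and t237l|10182 from 241 ± 71.6 to 25.3 ± 10.3 CPM (SD, n = 10). For each of these 3 transcripts the 10 fish of one strain all lay outside the range of the other strain. Each of the 3 also carries the tag of a fish of the strain in which it was higher. A bias from such tags is open, as described below. The fourth named transcript, t174l|2056, carries a House Creek tag but was higher in ARS-KO.

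By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change of t114l|3755 was 7.46 (SE 1.15, adjusted p = 0.00482). That of t235l|18680 was -3.92 (SE 0.457, adjusted p = 9.47e-05) and that of t237l|10182 was -3.25 (SE 0.286, adjusted p = 2.1e-06). The most abundant of the called transcripts, t174l|2056, was named after its values were seen. It reached 21760 ± 30340 CPM in ARS-KO against 386 ± 222 in House Creek (SD, n = 10), with a log2 fold change of 5.82 (SE 1.07, adjusted p = 0.0176). Of its summed CPM over all fish, 96% came from ARS-KO replicates 5 to 8, and without these 4 fish its log2 fold change was 1.13 (adjusted p = 0.159). Most other called transcripts changed modestly: 12 of the 20 had an absolute log2 fold change under 2 and 4 had one of at least 4. Of these 4, t174l|2056 and the transcript with the largest fold change of all calls (9.11) took 96% and 99.7% of their CPM from ARS-KO replicates 5 to 8. In 9 of the 20 the strains did not overlap in CPM, 5 higher and 4 lower in ARS-KO. Among all tested transcripts 22 showed no overlap, where chance gives a share of 0.00108% if fish are freely exchangeable. Code prefixes break that assumption: T9 and T23 against T11 and T17, a split that mixes the strains, gave 10 such transcripts, and T9 and T17 against T11 and T23 gave 2. At an unadjusted p under 0.05 there were 1226 transcripts, where 526 would be expected by chance if fish were independent. Between prefixes within a strain there were 1504 of 9991 in ARS-KO and 973 of 13850 in House Creek, so an excess can arise without a strain difference. The median log2 fold change of all tested transcripts was -0.08.

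**Figure D3:**
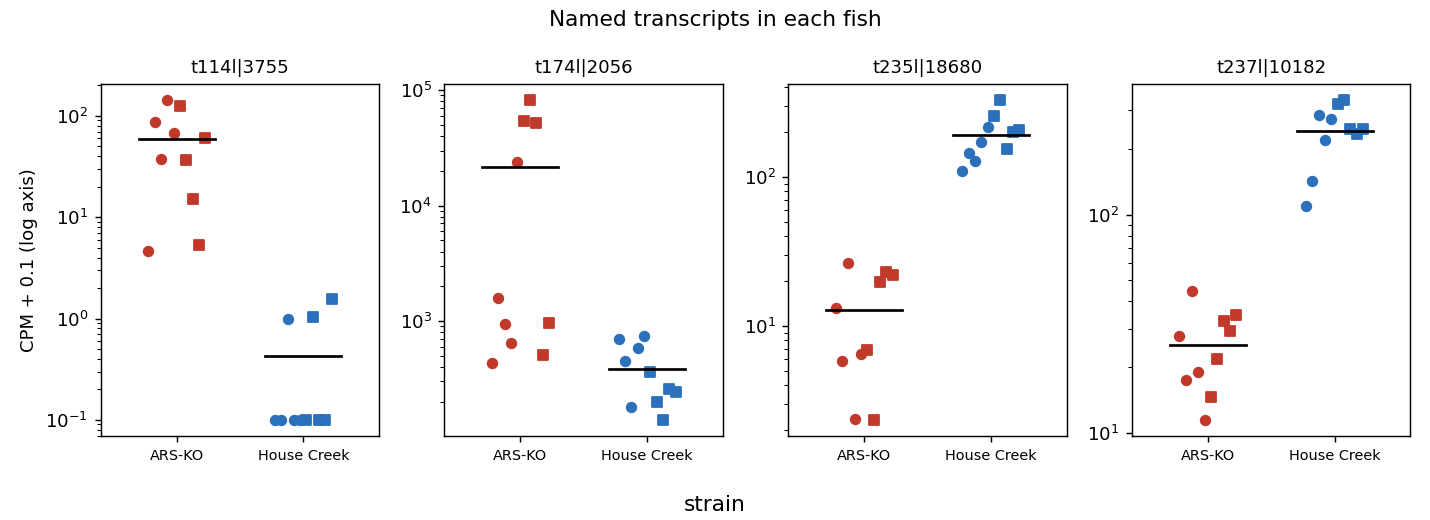
CPM plus 0.1 on a log axis for the 4 named transcripts in each fish, by strain, with circles for prefixes T9 and T17, squares for T11 and T23 and a bar at the strain mean. The strains do not overlap for t114l|3755, t235l|18680 and t237l|10182, while for t174l|2056 4 ARS-KO fish lie between 24050 and 82750 CPM and the highest of the other 16 fish is at 1572.

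Every fish of a code prefix belongs to one strain, so strain and prefix could not be separated within a prefix. With counts summed per prefix edgeR called 0 of 48186 transcripts (2938 at an unadjusted p under 0.05). That fit rests on only 4 sums and tests more transcripts than the main one (10513), so its 0 calls say little about strain. In limma-voom with a correlation of 0.14 within prefixes, 7 were called, all lower in ARS-KO, and 4 of the 20 strain calls were among them. These included t235l|18680 and t237l|10182. None of the 13 strain calls higher in ARS-KO passed, t114l|3755 among them (adjusted p = 0.0945). The 20 strain calls became 255 without ARS-KO replicates 5 to 8 (98 higher, 157 lower), 52 without ARS-KO replicate 7 and 39 without the 7 fish low on component 1. DESeq2 gave 103 of the 16795 transcripts left by its own filter (37 higher, 66 lower, 7 of the 20 shared). With limma-voom there were 131 (54 higher, 77 lower, 18 shared).

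**Figure D4:**
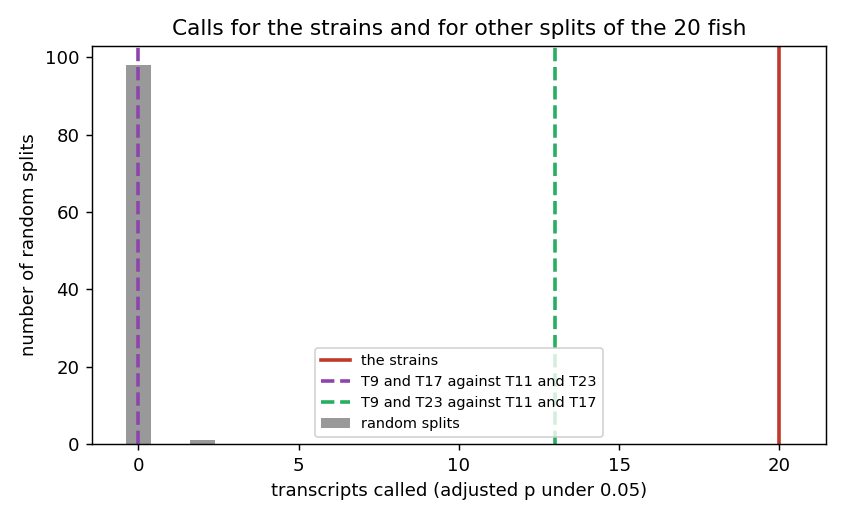
Number of transcripts called at an adjusted p under 0.05 (horizontal axis) against the number of random splits of the 20 fish into 10 and 10 (grey bars), with lines for the strains and for the 2 other splits that keep code prefixes whole. The strains give 20 calls, T9 and T23 against T11 and T17 give 13, T9 and T17 against T11 and T23 give 0, and no random split gives more than 2.

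Within ARS-KO, fish with prefix T11 differed from fish with prefix T9 in 208 of 9991 tested transcripts, 133 higher and 75 lower in T11. Transcript t234l|17857 stood at 13860 ± 4128 CPM in T9 fish and at 10.3 ± 7.82 CPM in T11 fish (SD, n = 5 each; log2 fold change -10.39, edgeR adjusted p = 0.000325). Transcript t114l|7040 had no count in any T9 fish and 607 ± 140 CPM in T11 fish (SD, n = 5; edgeR adjusted p = 0.000396). Set against a floor of 3 counts per library it was at least 877-fold higher in T11. Of the 208 transcripts 73 (35.1%) had no count in any fish of one prefix, 59 in T9 and 14 in T11. These were 0.731% of all transcripts tested and the 73 were all called. The count filter keeps a transcript absent from one prefix only if all 5 fish of the other reach its cutoff. This favours a call but does not fix it. Between the House Creek prefixes 89 transcripts had at least 3 counts in every fish of one prefix and 0 in the other. That number includes transcripts below the filter, and 0 of the 4 calls between those prefixes were of this kind. The share of 35.1% also depends on how many other transcripts were called. On simulated counts the test rarely reached smaller differences with 5 fish each, with prefix differences counted as noise there. At equal depth the T11 fish had counts for 38656 to 40436 transcripts, T9 replicates 1 to 4 for 19291 to 29872 and T9 replicate 5 for 43610.

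The median absolute log2 fold change of the 208 was 7.17 as fitted and 4.89 with those 73 transcripts at the bound given by the floor. None of the 208 (0) was among the 20 strain calls, all 20 of which were tested here. With 208 of 9991 called, few of 20 would be shared by chance. A large difference between prefixes also widens the spread within ARS-KO, which keeps a transcript from being a strain call. The 0 therefore says nothing about prefix effects among the strain calls. DESeq2 called 507 of the 24862 transcripts left by its own filter, and 1504 had an unadjusted p under 0.05 in the edgeR test. Leaving out ARS-KO replicate 4 gave 981 calls and leaving out replicate 5 gave 495. Without the 4 T9 fish low on component 1, 1 T9 fish was left, so the number of calls is not given. In that fit the median log2 fold change was 4.79 over 30435 tested transcripts, against 0.06 over 9991 in the main fit.

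Within House Creek, 4 of 13850 transcripts differed between prefixes, 2 higher and 2 lower in T23. Transcript t114l|1855 rose from 39.2 ± 14.7 CPM in T17 fish to 765 ± 468 CPM in T23 fish (SD, n = 5; log2 fold change 4.29, edgeR adjusted p = 0.048). Transcript t117l|10212 was at 13.6 ± 8.51 CPM in T17 and 0.0216 ± 0.0483 CPM in T23 (SD, n = 5; edgeR adjusted p = 0.048). At an unadjusted p under 0.05 there were 973 transcripts, and DESeq2 called 56 of the 13945 left by its own filter. The 4 calls did not hold with DESeq2 size factors in the edgeR fit (0 calls), after thinning to one total (0), without the 3 fish low on component 1 (0) or without any one of House Creek replicates 1 to 9 (0 calls each), and 3 were called without replicate 10, 1 of them among the 4. Whether the prefixes differed more in ARS-KO than in House Creek was not tested.

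Individual ARS-KO livers lay farther from the mean profile of their strain than House Creek livers did. The distance, a root mean square over transcripts in log2 CPM, was 1.88 ± 0.128 in ARS-KO and 1.65 ± 0.227 in House Creek (SD, n = 10; House Creek minus ARS-KO -0.235, two-sided permutation test, p = 0.0122). Measured from the mean of the code prefix the difference was -0.0392, and without the 7 fish low on component 1 it was -0.173, neither past the threshold.

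By the rule set beforehand, no transcript was found in one strain only. With at least 3 counts required in all 10 fish of one strain and 0 in all 10 of the other, the count was 0 in ARS-KO and 0 in House Creek, whereas 4429 transcripts had at least 3 counts in all 20 fish. When detection in 8 of the 10 fish sufficed, 11 transcripts qualified, 2 in ARS-KO and 9 in House Creek, and the ARS-KO libraries were shallower.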

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

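The random splits and the comparisons of code prefixes within a strain were planned, while the thinning of libraries, the tests of identifier tags and the 2 splits that keep prefixes whole and mix the strains were chosen after the strain result was seen.

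House Creek replicate 5 stood apart from the 9 other House Creek fish in 2 of the 22 groups of values examined, and chance puts about 1 in 20 such groups past the limit used. Its library held 18930000 counts, and its gap to the next fish was 0.622 of the range of the strain. Its most abundant transcript took 12.38% of its counts, with a gap of 0.507 of the range. Without this fish the strain comparison gave 18 calls.

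For the 20 strain calls, random regrouping argues against chance only if single fish can be exchanged freely. Of 100 splits of the 20 fish, the real one included, 1 gave as many calls, and the highest of the others gave 2. The random splits broke up the code prefixes, which the strains keep whole, so they do not test chance differences between prefixes. Deeper House Creek libraries do not account for the calls, since all 20 were called again after thinning every library to one total. A difference between sets of fish that share a code prefix stays open, because prefixes are nested in strain: the split of T9 and T23 against T11 and T17, which mixes the strains, gave 13 calls, and that of T9 and T17 against T11 and T23 gave 0. A bias from a transcript set built from these fish may contribute and is also open, since 65% of calls carry a tag of the strain in which they were higher against 55.8% of all tested transcripts (one-sided Fisher's exact test, p = 0.276), while direction went with tag strain within the 20 calls (p = 0.0443) and among 437 transcripts with an unadjusted p under 0.01 (p = 3.46e-13, transcripts not being independent). A genetic difference between the strains remains an untested biological alternative.

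For the prefixes within ARS-KO, 1 of 100 splits of the 10 fish, the real one, gave as many as 208 calls, and the highest of the others gave 27. After thinning to one total, 91.3% of the 208 were called again, so uneven totals did not make most of the calls. Totals of the ARS-KO fish were close to begin with (5110000 to 6547000), so thinning removed little. It does not test the lower number of transcripts detected at equal depth in T9 replicates 1 to 4, which stays open as an explanation. For the prefixes within House Creek, 3 of 100 splits gave at least 4 calls, the highest of the others also giving 4, and 0 of the 4 calls were called again after thinning. For transcripts found in one strain only, the real count was 0 and the highest of the others was 0, so all 100 splits reach it by construction and the comparison says nothing about chance.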

How the results depend on the processing

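Fits without 7 or 4 fish, with surrogate variables or with thinned libraries were chosen after seeing the data. The 20 strain calls (65% higher in ARS-KO) stayed within 1.5 times that number with DESeq2 size factors, a filter of 10 counts in 10 fish (11098 tested, so not stricter than the main one), a minimum log2 fold change of 1, thinning and without the 20 most abundant transcripts. Of the moves below the cause was not tested. Upper-quartile scaling gave 29 (22 higher, 7 lower) and library totals alone 37 (13 higher, 24 lower), and the median log2 fold change of all transcripts moved from -0.08 to 0.04 and -0.23. DESeq2 gave 103 (35.9% higher), limma-voom 131 (41.2% higher), limma-voom with the prefix correlation 7, sums per prefix 0 and an adjusted p under 0.01 gave 8. No filter gave 54471, of which 44017 had counts in 1 or 2 fish only. Leaving out T9 gave 58 and T11 91, while without T17 and T23 there were 18 each, sharing 4 and 6 with the 20. Leaving out single fish gave 14 to 52, the highest without ARS-KO replicate 7. Without the 7 fish low on component 1 there were 39, without ARS-KO 5 to 8 255 (17 shared) and with 2 surrogate variables 41. The direction of the 4 named transcripts was kept in every alternative run that tested them, and t174l|2056 was not tested without the 20 most abundant transcripts. All 4 missed the threshold with sums per prefix (adjusted p = 0.743), the only miss for t235l|18680 and t237l|10182. t114l|3755 also missed it with the prefix correlation (0.0945) and without T17 (0.0801), and t174l|2056 with limma-voom (0.0728), the prefix correlation (0.458), the replicate block (0.381) and without T17 (0.182), T23 (0.389) or ARS-KO 5 to 8 (0.159). With sums per prefix the log2 fold changes stayed near the main ones (t114l|3755 7.68, t235l|18680 -3.88, t237l|10182 -3.22, t174l|2056 5.70). That of t114l|3755 was 7.996 with the prefix correlation and 6.86 without T17. That of t174l|2056 was 6.49 without T17 and 5.36 without T23. It fell to 3.596 with limma-voom, 3.591 with the prefix correlation, 3.15 with the replicate block and 1.13 without ARS-KO 5 to 8. With the replicate block the strain fit gave 5 calls (1 higher, 4 lower), the ARS-KO prefix fit 1 and the House Creek prefix fit 0. The numbers do not pair the fish: 3 of 10 same-numbered pairs correlated above 0.1 (range -0.276 to 0.301) and 0 matched best with its own number. The 208 ARS-KO prefix calls became 1232 with no filter, 507 with DESeq2, 98 without the fish low on component 1 and 152 to 981 without single fish (981 without replicate 4, 495 without 5). The 4 House Creek prefix calls became 0 with DESeq2 size factors, thinning or without the fish low on component 1, 246 with no filter, 56 with DESeq2 and 0 to 3 without single fish. The spread difference of -0.235 kept its sign throughout, was -0.0392 from prefix means and -0.173 without the 7 fish, both short of the threshold, and ran from -0.192 to -0.289 without single fish. The count of 0 transcripts in one strain only became 1 with at least 1 count, 11 with 8 of 10 fish and 0 to 2 without single fish (2 without ARS-KO replicate 9, 1 without ARS-KO replicates 6 or 7 or House Creek replicates 3 or 8). Sums per locus and the gene lists were not run, for want of loci or gene names.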

Other observations

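All tests of the transcripts shared by 4 fish were chosen after the values were seen, as were the tests on identifier tags and the held-out scores, while the tests of on/off transcripts were set before, with their second definition run first and the first one then adopted because it fits the test as written.

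Individual livers were placed by strain with transcripts chosen without them. Each fish in turn was set aside, the 200 transcripts with the largest strain difference relative to spread were chosen in the other 19 fish, and the fish was scored from 0 (House Creek mean) to 1 (ARS-KO mean). ARS-KO fish scored 0.815 ± 0.139 (SD, n = 10; range 0.564 to 1.05) and House Creek fish 0.160 ± 0.131 (range -0.0585 to 0.307), so all 10 ARS-KO and 0 House Creek fish lay above 0.5. The lowest ARS-KO scores were those of replicate 7 (0.564), replicate 5 (0.691) and replicate 8 (0.72). Fish with the same code prefix stayed in the set used for choosing, so the score measures prefix as well as strain.

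A set of 4 transcripts was very abundant in the same 4 fish, ARS-KO replicates 5 to 8, which come from both ARS-KO prefixes. Each was at 100 CPM or more in these fish and at least 10 times as high as in any of the other 16, and together they took 3.79% to 12.5% of the counts against at most 0.126% elsewhere. Carry-over of RNA from these fish into the other libraries does not account for the level of t174l|2056 there, since the ratio of the second most abundant member to it was 0.443 to 0.608 in the 4 fish and at most 0.127 in the 16 others. The set may be reads of 1 source shared by several copies, as no member's log2 ratio to t174l|2056 varied by more than 0.666 over the 4 fish. Whether that source is biological or arose in handling was not tested, and 2 of the 4 are among the strain calls, the second with only 5 of 10 ARS-KO fish beyond the House Creek median.

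On/off transcripts made up 10.8% of those tested: 1135 had no count in at least 3 fish and at least 20 CPM in at least 3 others, and 2 of them were strain calls. Of the 1135, 364 to 670 were at 0 in each of the 7 fish low on component 1, 391 in ARS-KO replicate 4 and 72 to 227 in each of the 12 others. After thinning of all libraries to one total 1118 were found, but thinning cannot turn a 0 into a count, so this cannot exclude differences in depth. The number of on/off transcripts at 0 in a fish had a Spearman correlation of -0.191 with its library total (permutation test, p = 0.417). Near-identical transcripts that compete for the same reads would give partners of opposite pattern and matched level: 20 had such a partner, against at most 3 in 100 permutations of the fish, but partner levels differed by a median of 2.06 on the log2 scale against 1.25 for random pairs (p = 0.967). A second definition, off in 5 to 15 fish at under 5% of the 90th percentile, gave 69 partners against at most 6 and closer levels (1.05 against 1.44, p = 0.041), and once patterns near those of component 1 or the prefixes were removed the excess of partners remained (17 against at most 4) but the match of levels did not (p = 0.693), so competition for reads stays open and no biological alternative was tested.

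Tested transcripts with the tag of a given fish mostly had higher levels in that fish. For 18 of the 20 tags the median log2 CPM of tested transcripts was higher in the fish of that code than in the other 9 fish of its strain (median difference 0.463, range -0.232 to 1.07; two-sided exact sign test, p = 0.000402). Over all transcripts with a tag, the share with any count averaged 16.9% in the fish of that code (range 7.38% to 26.7%) and 13.9% in the other 19 fish. It was higher in the fish of that code for 15 of 20 tags and lower for ARS-KO replicates 1 to 4 and House Creek replicate 6. Without the fish itself, the level in its strain minus that in the other strain was positive for all 10 House Creek tags (0.127 to 0.373) and for 1 of 10 ARS-KO tags (-0.223 to 0.0473). These differences were not set against the offset of all tested transcripts, whose median log2 fold change was -0.219 with limma-voom. The contrast between House Creek and ARS-KO tags therefore cannot show a bias limited to House Creek tags. Over all fish the median fitted log2 fold change was 0.04 for transcripts with ARS-KO tags and -0.14 for those with House Creek tags. Among 437 transcripts with an unadjusted strain p under 0.01, 65.4% were higher in the strain of their tag, against 55.8% of all tested, and of the 7 calls lower in ARS-KO all 7 carried a House Creek tag, as did 7 of the 13 higher ones (one-sided Fisher's exact test of direction against tag strain, p = 3.46e-13 and p = 0.0443, with transcripts taken as independent, which they are not).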
